A study of Homo sapiens with 22 samples.

How the data were processed

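The series combined a protein renaturation assay with sequencing of the nucleic acids that stayed with the renatured proteins. Per the labels' protocols, proteins came from human neural stem cells differentiated for 6 days (the EnStem-A line), were aggregated by RNase treatment and were then renatured with fragmented genomic DNA or total RNA of Jurkat cells, an established human T cell line. Soluble protein with its bound nucleic acid was captured by immunoprecipitation or on a nitrocellulose membrane. The antibodies were 4G8, which recognises the amyloid beta peptide, an antibody to the heavy neurofilament subunit (NF-H) and an antibody to tau, with mouse IgG and anti-GFP antibodies as controls. Of the 22 samples, 15 stand behind the 5 peak lists analysed here: 7 DNA samples (4G8 n = 2, IgG n = 2, membrane capture n = 2, membrane negative control n = 1) and 8 RNA samples (4G8, NF-H, tau and GFP, n = 2 each). The 7 RNA samples from neuron lysate (4G8 n = 1, NF-H n = 2, tau n = 2, IgG n = 2) were not analysed here. Samples were grouped by their titles. The series' design text pairs IgG with RNA and GFP with DNA, whereas the titles and the file headers pair IgG with DNA and GFP with RNA. The titles and headers were followed.

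Per the labels, DNA libraries were read with 300 bp and RNA libraries with 75 bp paired reads. Bowtie2 2.2.5, Trim Galore 0.3.7, FastQC and MACS2 are named in the submitters' processing notes for these samples, with genome build hg19. Peaks were called with MACS2 2.1.0.20140616 at a q value cutoff of 0.05, with subpeak calling, per the file headers. The authors pooled the replicates of a group before calling, per the file headers, so each list holds 1 value per peak and no value per replicate. No spread between replicates could be computed, and every test below covers the counting or placement of peaks alone. The DNA lists were called on fragments from read pairs and the RNA lists on extended tags with duplicates kept, per the file headers. Keeping duplicates lets amplified copies add to RNA peak height, and the different settings mean that DNA and RNA peak strengths were not compared.

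The fold enrichment in each list is the authors' deposited ratio of the summit pileup to the local control level. The −log10 q and −log10 p values are also the authors' deposited values. The pileup, a coverage signal at the summit, was made by the authors with the larger library set to be scaled towards the smaller, per the file headers. In the values, the RNA pileups carried the ratio of control to treatment depth and the membrane pileups 2 times that ratio (0.409), and the 4G8 DNA pileups were not scaled (a factor of 1). Dividing by these factors gave whole numbers within the rounding of the file in 100% of peaks of every list, and pileups are given below as these whole tags or fragments. These per-peak values are the authors' own and were used to describe, rank and filter peaks within a list. Folds of shared sites are also given side by side, ranked by the smallest and, between RNA lists, correlated, and each is relative to the depth and control of its own list.

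The depth per sample could not be separated because libraries were pooled. The pooled depth after filtering was 4973316 fragments for 4G8 DNA against 2993888 for IgG, and 2824980 for membrane capture against 578006 for its negative control, in which 18% of fragments were redundant. The pooled RNA depth was 7679087 tags for 4G8, 8163535 for NF-H and 5709540 for tau, each against the same 4827406 GFP tags. The estimated fragment length was 156 bp for 4G8, 144 bp for NF-H and 108 bp for tau RNA. A shared control enters all 3 RNA comparisons, so part of any likeness between RNA lists may come from it. Chance overlap with unchanged groups could not be simulated from peak lists.

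A peak was counted as a distinct interval. Intervals with several summits took the highest fold enrichment, −log10 q and pileup of their summits. Intervals were taken to overlap at 1 bp or more. The chance overlap of DNA peaks was measured with 10000 random placements of the peaks of the first-named list, with width kept, on the same chromosome outside the centromere gap and the unsequenced 10 kb ends, one-sided for more overlap. The smallest p this can give is 1.00e-04. Peaks outside chromosomes 1 to 22, X and Y were left out of placements. RNA lists were compared by shares of overlapping peaks, by the overlap of independent lists (n1 × n2 / N over regions with a peak in any RNA list) and by Spearman and Pearson correlations of log2 fold enrichment over shared peaks, with no p value. The number of peaks per chromosome was tested against the share of chromosome length by two-sided exact binomial tests. Shares of peaks between lists were tested by two-sided Fisher exact tests, and paired presence over the same DNA peaks or the same 48 chromosome ends by two-sided exact McNemar tests. Benjamini-Hochberg adjustment was applied within each family (24 chromosomes per list, 72 chromosome tests between RNA lists, 30 compartment tests, 6 tests of DNA peaks by RNA list, 3 tests of chromosome ends, 7 placement tests). Intervals of shares are 95% Wilson intervals and cover counting error only. The tests of counts treat peaks as independent, although peaks gathered in single regions, so their p values can overstate the evidence.

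No genome or annotation of build hg19 was used here, and the reference tables at hand are of another build. Peaks are therefore named by hg19 position, and no gene, exon, intron or repeat class was assigned to them. Tests of gene lists, of annotation classes and of base composition that had been set before the data were examined were not run for this reason. In place of annotation classes, peaks were assigned, after the data were seen, to parts of the assembly: within 12 kb of a chromosome end, within 1 Mb or 1 to 5 Mb of a centromere gap, the mitochondrial genome, unplaced contigs, and the remaining chromosome arms. Chromosome lengths and centromere gap positions of hg19 were entered by hand from general knowledge. They were checked on the peaks: 0 of 31697 lay past a chromosome length and 0 lay inside a gap. Such a check cannot show a gap that was entered too short. The peaks within 12 kb of an end lay 9588 to 10291 bp from it, around the 10 kb taken as unsequenced. The 4G8 RNA peak nearest to an end, on chromosome 17 at 81185467 to 81185622, lay wholly inside those 10 kb. That peak goes against an unsequenced 10 kb at every end. Other unsequenced stretches were kept in the lengths and in random placements; as an alternative added after the data were seen, stretches of over 8 Mb without a peak of any list were taken out of chromosome length.

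The rule for named peaks, set before the data were examined, took the 12 peaks with the highest fold enrichment in each list, the 5 loci with the most peaks (1 Mb bins here), the 10 regions in all 3 RNA lists with the highest smallest fold enrichment and the 10 loci in both DNA lists with the highest smaller fold enrichment. The text gives part of these, and names other peaks as chosen after their values were seen. Alternatives tried were stricter fold enrichment (5 or more) and −log10 q (5 or more), and other overlap rules (50% of the shorter peak, or within 1000 bp). Others were merging within 100 bp, placement anywhere in the genome or within 500 kb, and leaving out repeat-rich parts. Repeat-rich parts were those within 5 Mb of a centromere gap or 100 kb of a chromosome end, unplaced contigs and the mitochondrial genome. The overlap and placement code was tested on simulated data against the 7295 4G8 RNA peaks on chromosomes 1 to 22, X and Y: 100 of 100 planted overlaps were recovered, and 1 of 100 random sets gave p under 0.05. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.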

Results

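Genomic DNA and RNA that stayed with renatured proteins were recovered with antibodies to amyloid beta (4G8), NF-H and tau or on a membrane, and peaks over the matching control were listed for 5 comparisons. The DNA comparisons were 4G8 (n = 2) against IgG (n = 2) and membrane capture (n = 2) against a membrane negative control (n = 1). The RNA comparisons were 4G8, NF-H and tau (n = 2 each) against GFP (n = 2). Replicates were pooled before peak calling, so no value below has a spread between replicates. Pooled treatment depth was 4973316 fragments for 4G8 DNA and 2824980 for membrane DNA, and 7679087, 8163535 and 5709540 tags for 4G8, NF-H and tau RNA. All positions are on build hg19, and no gene was assigned to a peak.

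The 4G8 DNA list held 6692 peaks and the membrane DNA list 160. The RNA lists held 7305 peaks for 4G8, 8406 for NF-H and 9292 for tau. Counting every summit gave 7056, 199, 7679, 8937 and 9866 in the same order. Median peak width was 228 bp for 4G8 and 347 bp for membrane DNA, and 177 bp for 4G8, 173 bp for NF-H and 136 bp for tau RNA. The smallest widths, 184, 185, 156, 144 and 108 bp in the same order, lay at or next to the fragment lengths used in calling (184, 183, 156, 144 and 108 bp), so the order of widths between lists is partly set by calling. Median fold enrichment over the control was 4.49 in the 4G8 DNA list, 6.62 in the membrane list, 6.62 in the 4G8 RNA list, 6.08 in the NF-H list and 5.86 in the tau list. Fold enrichment of 5 or more was reached by 39.6% of 4G8 DNA peaks and 90.0% of membrane peaks. Among RNA peaks it was reached by 78.4% with 4G8, 69.1% with NF-H and 67.2% with tau. The DNA and RNA lists were called with different settings, so their folds are not compared. The median 4G8 DNA summit held 8 fragments, so the 4G8 DNA list rested on shallow coverage. At a −log10 q of 5 or more, 1095 of its 6692 peaks were left.

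Which DNA sites were recovered with 4G8 was asked first. The highest fold enrichment over IgG, 29.2, lay on chromosome 5 at 180472914 to 180473357, with 46 fragments at the summit. Peaks on chromosome X at 6450829 to 6451603 and on chromosome 17 at 154743 to 155116 followed, both at 18.7. The next were on chromosome 22 at 19189888 to 19190111, with 28 fragments at the summit, and on chromosome 11 at 68844333 to 68844788, with a fold of 17.1. The chromosome 11 peak was the one among these 5 that overlapped RNA peaks, and it did so in all 3 RNA lists. Among the 12 peaks with the highest fold, 1 overlapped the membrane list, on chromosome 9 at 140610566 to 140611052 with a fold of 13.8.

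The 4G8 DNA peaks were spread unevenly over chromosomes. Chromosome 19 held 268 of 6582 peaks, 2.13 times the number expected from its length (adjusted p = 6.77e-28, exact binomial test). Chromosomes 16, 17, 20 and 22 held 1.78, 1.82, 1.79 and 1.68 times the expected number. Chromosome X held 107 peaks, 0.324 times the expected number (adjusted p = 1.28e-46, exact binomial test), and chromosome 5 held 0.603 times. In all, 14 of 24 chromosomes differed from their share of length, 6 above and 8 below it. When peaks within 1 Mb of each other were counted once, which left 1765 loci, 2 chromosomes differed, X at 0.610 and Y at 0.207 times the number expected from full length. Of 151 membrane peaks, 11 lay on chromosome 16 and 8 on chromosome 21, and 0 of 24 chromosomes passed the adjusted test. Full length includes stretches that hold no peak of any list, such as 28816731 to 58822230 of chromosome Y. Without such stretches of over 8 Mb, Y held 0.637 and chromosome 22 held 2.32 times the expected number of 4G8 DNA peaks, and chromosomes 16, 21 and 22 passed the test in the membrane list, at 2.73, 4.01 and 3.86 times (adjusted p = 0.0206 each, exact binomial test). Copy number of the Jurkat genome and mappability were not used here.

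DNA peaks also gathered in single regions. The 1 Mb bin with the most 4G8 DNA peaks ran from 2 to 3 Mb of chromosome 1, with 40 peaks and a median fold of 5.09. The bin from 49 to 50 Mb of chromosome 4, next to the centromere gap, held 32 peaks with a median fold of 1.68. The bin from 46 to 47 Mb of chromosome 16 held 28 peaks with a median fold of 1.97. Its first peak directly followed a stretch without peaks of any list, 34257235 to 46386279. These peaks lay at least 8.05 Mb from the centromere gap as entered, so they were counted as chromosome arm and not as repeat-rich. Of all 4G8 DNA peaks, 3.60% lay within 1 Mb of a centromere gap and 1.51% on unplaced contigs. Of the 160 membrane peaks, 8 lay on unplaced contigs (5.00%, 95% Wilson interval 2.56 to 9.56%).

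Membrane capture, which takes up proteins without an antibody, and 4G8 immunoprecipitation had separate controls, so their shared sites could be counted. Of the 160 membrane peaks, 89 overlapped a 4G8 DNA peak (55.6%, 95% Wilson interval 47.9 to 63.1%). The highest smaller fold of the shared sites was on chromosome 17 at 80544118 to 80544361, at 9.28 on the membrane and 10.9 with 4G8. It was followed by chromosome 14 at 91759486 to 91759933 (9.66 and 8.79) and chromosome 1 at 4692649 to 4693192 (8.52 and 8.34). Chromosome 9 at 140610711 to 140610914 had folds of 8.22 and 13.8, and chromosome 16 at 88271021 to 88271247 had folds of 7.78 and 9.95. The strongest membrane peak, on chromosome 22 at 42719894 to 42720272 with a fold of 20.2, had no 4G8 DNA peak, whereas the next 3, on chromosome 10 at 134177873 (18.4), chromosome 1 at 31904630 (16.8) and chromosome 16 at 1002788 (15.4), each had one.

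On chromosomes 1 to 22, X and Y, 81 of 151 membrane peaks overlapped a 4G8 DNA peak, against a mean of 0.279 and at most 4 in 10000 random placements on the same chromosome (permutation p = 1.00e-04, the smallest these placements can give, one-sided). With fold enrichment of 5 or more required in both lists, the share fell from 53.6% to 23.0% (32 of 139 peaks), with the same permutation p of 1.00e-04. With a −log10 q of 5 or more required in both lists it was 55.1% (43 of 78 peaks, permutation p = 1.00e-04).

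**Figure D1:**
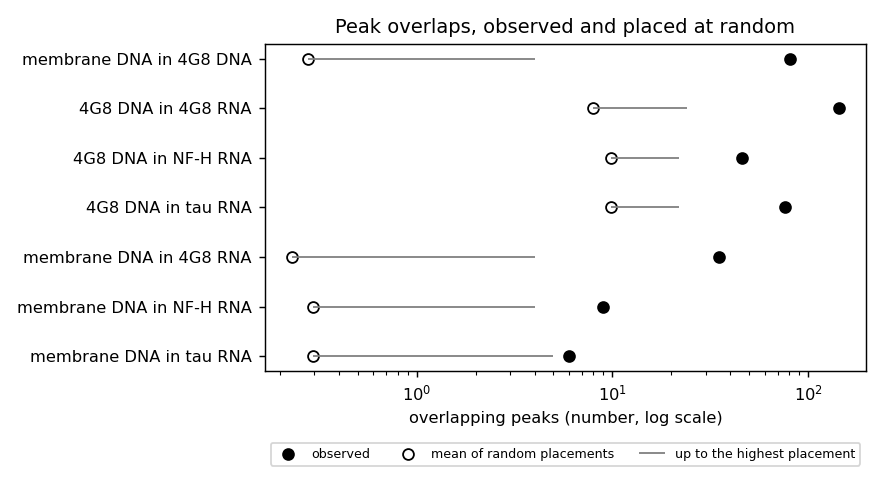
Number of DNA peaks that overlapped a peak of another list (x axis, log scale) for 7 pairs of lists (y axis). Filled points are observed numbers, open points the mean of 10000 random placements on the same chromosome, and lines reach the highest placement. The membrane list overlapped the 4G8 DNA list with 81 peaks against a mean of 0.279.

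For RNA, the strongest sites were largely shared by the 3 antibodies. Of the 12 peaks with the highest fold in each list, 10 of the 4G8 list, 12 of the NF-H list and 11 of the tau list overlapped peaks of both other RNA lists. Chromosome 20 at 32685237 to 32685464 had folds over GFP of 37.0 with 4G8, 29.7 with NF-H and 33.3 with tau. Chromosome 2 at 136378989 to 136379217 had folds of 37.7, 28.9 and 40.6 in the same order. Other sites on that chromosome, at 216992203 to 216992436 (35.5, 33.8 and 28.5) and 153519555 to 153519821 (40.5, 28.4 and 32.7), ranked next. Further sites high in all 3 lists lay on chromosome 18 at 9950332 to 9950604 (31.8, 26.9 and 26.3), chromosome 10 at 120816269 to 120816667 (30.7, 26.2 and 31.4) and chromosome 1 at 214795366 to 214795661 (47.7, 25.2 and 24.2). The single strongest 4G8 peak, on chromosome 2 at 240587014 to 240587409 with a fold of 53.9, had no peak in the other lists.

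Merging the RNA lists gave 16264 regions, of which 2344 (14.4%) held a peak of all 3 antibodies. A further 2349 regions held NF-H and tau peaks without 4G8, 972 held 4G8 and tau and 556 held 4G8 and NF-H. Regions called with 1 antibody numbered 3412 for 4G8, 3121 for NF-H and 3510 for tau. Of the 8406 NF-H peaks, 56.1% overlapped a tau peak (95% Wilson interval 55.1 to 57.2%) and 34.8% a 4G8 peak. Of the 7305 4G8 peaks, 45.6% overlapped a tau peak and 39.9% an NF-H peak.

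**Figure D2:**
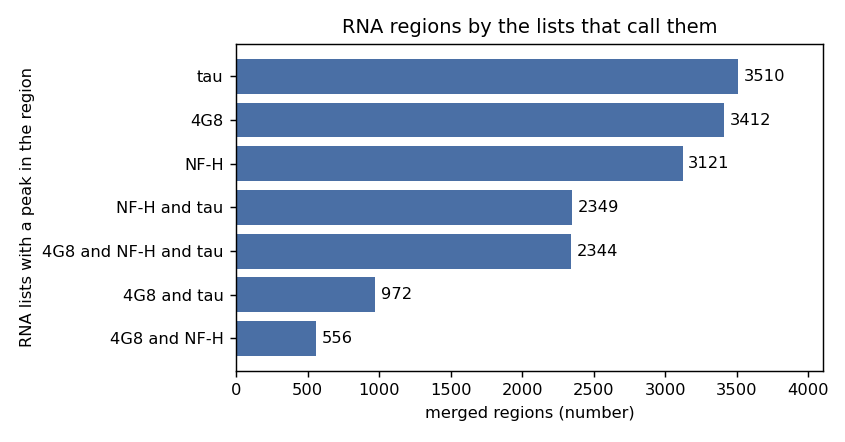
Number of merged RNA regions (x axis) by the set of RNA lists with a peak in the region (y axis). Regions called with tau alone (3510), 4G8 alone (3412) and NF-H alone (3121) outnumber the 2344 regions called in all 3 lists.

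Random placement of the peaks gave a mean of 8.71 4G8 peaks on NF-H peaks, 8.52 4G8 peaks on tau peaks and 10.9 NF-H peaks on tau peaks, against 2908, 3321 and 4704 observed on chromosomes 1 to 22, X and Y. Over the 16264 regions, independent lists would share 3749 regions for 4G8 and NF-H, 4109 for 4G8 and tau and 4722 for NF-H and tau, against 2900, 3316 and 4693 observed. A region enters this count by being called at least once, which keeps N small and so raises the numbers of independent lists. Within the regions of the remaining list, the odds ratio of the pair was 3.60 for 4G8 with NF-H, 5.60 for 4G8 with tau and 14.8 for NF-H with tau. Across shared peaks, which are not independent replicates, log2 fold enrichment correlated with a Spearman rho of 0.668 (Pearson r = 0.714) over 2917 peaks of 4G8 and NF-H, 0.678 (r = 0.730) over 3331 of 4G8 and tau and 0.704 (r = 0.730) over 4717 of NF-H and tau. All 3 lists used the same GFP libraries and the same RNA pool, so part of this overlap and correlation may come from them.

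Peaks within 1 Mb of a centromere gap made up 3.98% of the 4G8 list (291 of 7305), 0.595% of the NF-H list (50 of 8406) and 1.07% of the tau list (99 of 9292). The difference from NF-H had an odds ratio of 6.93 (adjusted p = 6.27e-50, Fisher exact test) and that from tau 3.85 (adjusted p = 4.94e-34). NF-H and tau also differed from each other (adjusted p = 0.00256, Fisher exact test). In the 4G8 DNA list the share was 3.60%, and its difference from the 4G8 RNA list did not pass the test (adjusted p = 0.395, Fisher exact test). Each RNA list held 0 peaks on unplaced contigs and the 4G8 DNA list 101, so the DNA and RNA shares may not be like for like. At fold enrichment of 5 or more the shares near a gap were 1.77% for 4G8 DNA and 3.11% for 4G8 RNA (Fisher exact p = 3.49e-04). That cut kept 39.6% of 4G8 DNA and 78.4% of 4G8 RNA peaks, called with different settings, so this difference may come from the fold scales. Of the 291 4G8 peaks, 32 lay on chromosome Y and 42 on chromosome 4, where the bin from 49 to 50 Mb held 40 4G8 peaks with a median fold of 3.69. The Fisher tests took such clustered peaks as independent, so their p values can overstate the evidence.

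Peaks at chromosome ends, where the assembly begins with telomeric repeats on many arms, were present at 12 ends with 4G8, 9 with NF-H and 1 with tau. The start of chromosome 7, at 10001 to 10347, had folds of 53.5 with 4G8, 21.2 with NF-H and 5.59 with tau. The start of chromosome 1 had folds of 40.9 with 4G8 and 17.1 with NF-H, and that of chromosome 4 22.2 and 7.60. All 9 ends with an NF-H peak also had a 4G8 peak. Over 48 ends, 4G8 had 11 that tau lacked and tau 0 that 4G8 lacked (adjusted p = 0.00293, exact McNemar test), and NF-H had 8 that tau lacked (adjusted p = 0.0117). The 3 ends that 4G8 had and NF-H lacked gave an adjusted p of 0.250. With fold enrichment of 5 or more required, NF-H had 5 ends that tau lacked (exact p = 0.0625), and 4G8 had 6 that NF-H lacked (exact p = 0.0312). These tests were chosen after the peaks had been seen. They took the ends as independent, although ends with the same repeats may share reads, so their p values can overstate the evidence.

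**Figure D3:**
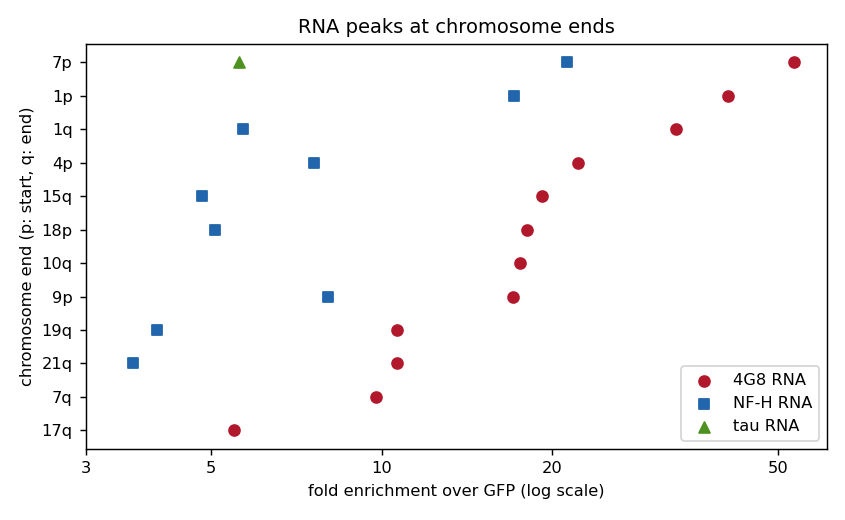
Fold enrichment over GFP (x axis, log scale) of RNA peaks within 12 kb of a chromosome end (y axis, p for the start and q for the end of a chromosome). Each point is 1 peak of the 4G8, NF-H or tau list, and 12 ends have a 4G8 peak, 9 an NF-H peak and 1 a tau peak.

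The spread of RNA peaks over chromosomes differed between 4G8 and the other antibodies, and the 4G8 list lay nearest to a spread by full chromosome length. Its total variation distance was 0.0753, against 0.156 for NF-H and 0.139 for tau. This distance is a scaled sum of the absolute differences between each chromosome's share of peaks and its share of length. Chromosome 19, a gene-dense chromosome, held 5.16% of NF-H peaks and 4.72% of tau peaks but 2.37% of 4G8 peaks (odds ratio 0.447 against NF-H, adjusted p = 9.26e-19, Fisher exact test). Chromosomes 16 and 17 held 2.58% and 3.67% of 4G8 peaks against 4.48% and 5.92% of NF-H peaks. Chromosome Y held 131 4G8 peaks against 8 NF-H and 8 tau peaks, and 32 of the 131 lay within 1 Mb of the centromere gap. These were 0.936, 0.0497 and 0.0450 times the number expected from its full length and 1.79, 0.0951 and 0.0861 times that number without the stretches that hold no peak. In total, 17 of 24 chromosomes differed between 4G8 and NF-H, 13 between 4G8 and tau and 0 between NF-H and tau after adjustment. At fold enrichment of 5 or more these numbers were 7, 6 and 0, and chromosomes 16, 17, 19 and Y were among both the 7 and the 6. Clustered RNA peaks were counted one by one in these tests, so the p values can overstate the evidence. The 4G8 DNA list lay at a distance of 0.127, further from length than the 4G8 RNA list. Whether genomic DNA in the 4G8 RNA libraries contributes to the differences, taken up below, stays open.

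**Figure D4:**
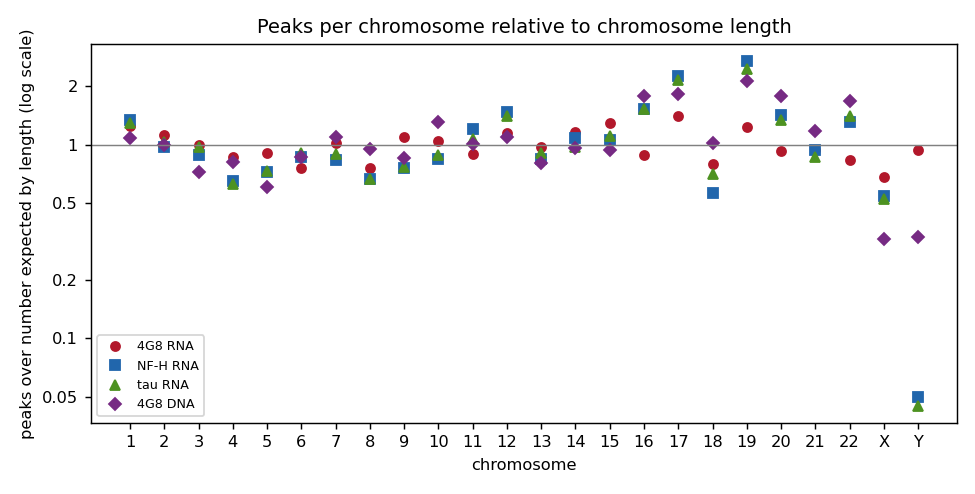
Number of peaks over the number expected from full chromosome length (y axis, log scale) for each chromosome (x axis) in the 4G8, NF-H and tau RNA lists and the 4G8 DNA list, with a line at 1. On chromosome Y the 4G8 RNA list lies at 0.936 and the NF-H and tau lists at 0.0497 and 0.0450.

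Whether 4G8 recovered the same sites from DNA and RNA was addressed by the overlap of those lists. Of 6582 4G8 DNA peaks on chromosomes 1 to 22, X and Y, 144 overlapped a 4G8 RNA peak (2.19%), against a mean of 7.96 in random placements (permutation p = 1.00e-04, one-sided). The share was 4.93% (51 of 1034 peaks) with a −log10 q of 5 or more required in both lists and 3.69% when peaks within 1000 bp of each other were counted, with the same permutation p. The NF-H and tau RNA lists overlapped 46 and 76 of the same DNA peaks, against means of 9.83 and 9.81 (permutation p = 1.00e-04 each, adjusted p = 1.00e-04 each). Over all 6692 DNA peaks, 126 were overlapped by 4G8 RNA and not by NF-H RNA and 27 the other way round (adjusted p = 1.03e-15, exact McNemar test). Against tau RNA the numbers were 113 and 45 (adjusted p = 1.86e-07, exact McNemar test). Tau RNA overlapped more of them than NF-H RNA, with 62 against 31 (adjusted p = 0.00206, exact McNemar test). Genomic DNA in the 4G8 RNA libraries, taken up below, could also raise the 4G8 overlap. These counts therefore do not show that 4G8 recovered the same sites from DNA and RNA.

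Membrane DNA peaks, recovered without an antibody, were also overlapped most often by 4G8 RNA. The 4G8 RNA list overlapped 36 of 160 membrane peaks (22.5%, 95% Wilson interval 16.7 to 29.6%), the NF-H list 10 (6.25%) and the tau list 7 (4.38%). The difference from NF-H rested on 28 peaks against 2 (adjusted p = 1.30e-06, exact McNemar test) and that from tau on 31 against 2 (adjusted p = 2.62e-07, exact McNemar test), while NF-H and tau did not pass the test against each other (6 against 3, adjusted p = 0.508). With fold enrichment of 5 or more required of RNA peaks, the 28 fell to 18 (exact McNemar p = 7.63e-05) and the 31 to 20 (exact p = 2.10e-05), and with a −log10 q of 5 or more to 15 (exact p = 6.10e-05) and 19 (exact p = 2.21e-04). Sites called on the membrane, with 4G8 DNA and with 4G8 RNA included chromosome 1 at 4692649 to 4693192 (folds of 8.52, 8.34 and 9.63), chromosome 7 at 158152813 to 158153538 (7.76, 11.8 and 6.79) and chromosome 11 at 1093000 to 1093424 (7.11, 6.22 and 13.4). These sites and these tests of RNA lists against each other were chosen after the data had been seen.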

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

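Of the tests in this part, those on tau depth, on the covered length of the 4G8 RNA list, on peaks near centromere gaps in the tau list, on broad and narrow peaks of like depth, on genomic DNA in the 4G8 RNA libraries, on the overlap of membrane with 4G8 DNA peaks without repeat-rich parts and on that overlap by −log10 q and among deep peaks were chosen after the values behind them had been seen, as were the comparisons between RNA lists themselves.

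Chromosome-end RNA peaks differed between antibodies: 12 ends had a 4G8 peak and 1 a tau peak (adjusted p = 0.00293, exact McNemar test). That test took the ends as independent, although ends with the same repeats may share reads. Thinned to the tau depth, 11 of the 12 4G8 end peaks would still reach the median tau peak of 17 tags, which argues against a lower tau depth as the cause. Of the 2440 broadest 4G8 peaks away from the ends, 65.9% were also in the tau list against 14.5% of the 2455 narrowest. Among peaks of like depth the broad ones were ahead at 14 to 20 summit tags (42.4 against 17.6%). They were also ahead at 21 to 36 tags (69.0 against 44.7%). At 37 tags or more they were again ahead (88.4 against 74.8%) but deeper (median 64 against 50 tags). The 2111 peaks of 7 to 13 tags had too many tied widths to compare. The lower quartile of 4G8 peak width, 156 bp, equals the fragment length, so narrow peaks can be duplicate tags stacked at a single position. Such peaks may be absent from another list whatever its fragment length, so the comparison cannot decide on shorter tau fragments. Other trimming of repeats in the tau libraries cannot be told apart from the antibody, since the tau share within 1 Mb of a centromere gap, 1.07%, lay below that of 4G8 (3.98%) and above that of NF-H (0.595%). A difference between the proteins in binding telomeric RNA stays open and was not tested.

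Membrane DNA peaks were overlapped by the 4G8 RNA list more often than by the NF-H list, 36 against 10 of 160 (adjusted p = 1.30e-06, exact McNemar test). The covered length of the 4G8 list was 0.917 times that of the longer other list, which argues against length as the cause. Leaving out repeat-rich parts kept 30 against 7 of 130 peaks (exact McNemar p = 5.65e-06), which argues against collapsed repeats in those parts. Repeats elsewhere, such as those further than 100 kb from a chromosome end, were kept and stay open. Genomic DNA in the 4G8 RNA libraries stays open. Regions called with 4G8 alone lay nearer to a spread by chromosome length than those with NF-H alone. The difference in total variation distance was -0.0857 (95% bootstrap interval -0.109 to -0.0627). Without stretches that hold no peak it was -0.0765 (interval -0.0985 to -0.0518). The lists from genomic DNA lay further from length, at 0.127 for 4G8 DNA and 0.236 for membrane DNA, against 0.103 for 4G8 RNA alone. Nearness to length therefore does not mark genomic DNA, and the comparison cannot decide. Binding of the same sites as DNA and RNA by 4G8-recovered protein stays open and was not tested.

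The 4G8 DNA and membrane lists shared sites far above placement at random. Collapsed repeats in the repeat-rich parts left out are argued against by a share of 50.8% without them (95% Wilson interval 42.3 to 59.2%). Repeats elsewhere were kept and stay open, and 66 of 151 membrane peaks lay within 5 Mb of a chromosome end. Regional copy number is argued against by an observed number 87.3 times that of placements within 500 kb. Sites that are well covered in any Jurkat DNA library cannot be told apart from sites bound in both captures: the share of 4G8 DNA peaks that overlap the membrane list was 1.32% in the 2430 with the highest fold and 1.85% in the 2270 with the lowest, a ratio of 0.712 (95% interval 0.449 to 1.13), but 3.36% in the 2231 with the highest and 0.311% in the 2248 with the lowest −log10 q. Depth enters both measures, with a median of 50 fragments in overlapping and 7 in other peaks. By summit fragments, all 89 overlapping peaks lay among the 2373 deepest, against 0 of the next 1876 and 0 of the lowest 2443. These groups by depth were chosen after the data had been seen. At 69 fragments or more the share was 42.9% in the 56 highest-fold and 3.57% in the 56 lowest-fold peaks (Fisher exact p = 6.95e-07). It was 30.9 and 17.9% at 33 to 68 fragments (Fisher exact p = 0.126). At 20 to 32 fragments it was 13.3 and 10.2% (Fisher exact p = 0.777). Binding of the same DNA by proteins taken up in both captures stays open and was not tested.

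Other differences between the 4G8 and NF-H RNA lists were tested as well. The share of peaks within 1 Mb of a centromere gap differed, at 3.98% against 0.595% (adjusted p = 6.27e-50, Fisher exact test). The share on chromosome 19 differed, at 2.37% against 5.16% (adjusted p = 9.26e-19, Fisher exact test). The share on chromosome Y differed, at 1.80% against 0.0953% (adjusted p = 1.39e-32, Fisher exact test). Relative to full length, chromosomes 19 and Y held 1.24 and 0.936 times the expected number with 4G8, against 2.70 and 0.0497 with NF-H. Without stretches that hold no peak, Y held 1.79 times with 4G8. The 4G8 DNA list held 2.13 times the expected number on chromosome 19 and 0.333 times on Y (0.637 without those stretches). Genomic DNA spread like that list would therefore not account for the 4G8 RNA shares on chromosomes 19 and Y. Its share near a centromere gap, 3.60%, did lie near that of 4G8 RNA. Genomic DNA of another spread was not tested and stays open. These tests took clustered peaks as independent.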

How the results depend on the processing

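Over 25 results, 81 alternatives were run, 46 set before the data were examined and 35 added after. Of these, 64 left the result on its side of the threshold, within its error or, for a count, within 1.5 times. Another 17 changed it, and 0 reversed it. A reversal could be recorded only for overlaps against placement, shares near centromere gaps, chromosome ends and membrane peaks overlapped by RNA. Counts of peaks or chromosomes, RNA overlap shares and correlations could only stay or move. No paired analysis was possible because the authors pooled replicates 1 and 2 of each group before calling peaks, so leaving out a replicate was not possible either. Alternatives on gene lists, genes as units, annotation classes and base composition were not run, since no hg19 annotation or sequence was used here. For the overlap of 4G8 DNA with membrane and with 4G8 RNA peaks the permutation p was 1.00e-04 under each alternative, the smallest it can be, so it does not show how far the overlap moved: the first share ranged from 23.0% (fold 5 or more in both lists) to 55.6% around 53.6%, and the second from 1.87% to 4.93% (−log10 q of 5 or more in both) around 2.19%. At fold enrichment of 5 or more, the 4G8 DNA list fell to 2651 peaks. At −log10 q of 5 or more, 1095 4G8 DNA, 85 membrane and 5887 tau peaks were left. At that q in both lists, 47.3% of 4G8 peaks overlapped NF-H, 51.1% of 4G8 peaks overlapped tau and 53.6% of NF-H peaks overlapped tau. At fold 5 or more in both, 48.5% of NF-H peaks overlapped tau. Among merged regions that also held a peak of the third list, 70.7% of 4G8 regions held NF-H and 80.8% held tau. The share of NF-H regions with tau, 80.8%, is the same fraction (2344 of 2900). These are shares of regions already called in a further list, so they are not set against the shares of peaks. Counting 4G8 DNA peaks within 1 Mb once left 2 chromosomes of 14 past the threshold, with fewer and evenly capped loci. Chromosome length without stretches of over 8 Mb that hold no peak put 3 chromosomes past the threshold in the membrane list, against 0. At fold 5 or more, 7 chromosomes differed between 4G8 and NF-H RNA and 6 between 4G8 and tau, with fewer peaks tested; 5 ends had an NF-H and no tau peak (exact p = 0.0625), and 6 ends a 4G8 and no NF-H peak (exact p = 0.0312). The 4G8 DNA list, with a median of 8 fragments per summit, and the membrane control of 578006 fragments limit what could be called.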

Other observations

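The counts in this part were chosen after the data had been seen, except the bin with the most membrane peaks, which the rule for named peaks gave. DNA peaks lay near chromosome ends more often than placement gave. Within 5 Mb of an end lay 66 of 151 membrane peaks (43.7%), against a mean of 14.3 in 10000 random placements on the same chromosome, 4.60 times as many (permutation p = 1.00e-04, one-sided). The 4G8 DNA list had 1223 of 6582 peaks there (18.6%), 2.13 times the placed mean, and the 4G8, NF-H and tau RNA lists had 11.8%, 12.8% and 13.2%, which were 1.48, 1.51 and 1.57 times theirs (permutation p = 1.00e-04 each). The bin with the most membrane peaks, 134 to 135 Mb of chromosome 10, held 4 peaks with a median fold of 8.71.

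Regions called with a single RNA antibody met DNA peaks unequally. On chromosomes 1 to 22, X and Y, of the 3412 regions with 4G8 alone, 120 (3.52%) overlapped a 4G8 DNA peak, against 26 of 3121 (0.833%) with NF-H alone, 50 of 3508 (1.43%) with tau alone and 10 of 2336 (0.428%) in all 3 lists. The membrane list overlapped 27, 2, 2 and 2 of the same sets. Genomic DNA in the 4G8 RNA libraries could also give the higher 4G8 numbers and was not told apart from binding.

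Some RNA peaks were very deep and little above the control. The deepest NF-H peak, on chromosome 9 at 79186691 to 79186834, held 140669 tags, 1.72% of the treatment tags, at a fold of 1.58. The tau list had 78531 tags on chromosome 1 at 120543973 to 120544081 (fold 1.95), 76569 on chromosome 9 from 79186728 (fold 1.35), at the same site as the deepest NF-H peak, and 75410 on chromosome 12 at 127650556 to 127650665 (fold 1.97). The deepest 4G8 peaks lay on the mitochondrial genome, led by 13379 tags at 2067 to 2471 with a fold of 1.42. Peaks of 1000 tags or more numbered 21 for 4G8, 65 for NF-H and 55 for tau, of which 6, 21 and 24 had a fold under 2. The mitochondrial genome held 10 4G8, 13 NF-H and 16 tau peaks, with median folds of 2.03, 1.55 and 2.11.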
